A study of Rattus norvegicus with 16 samples.

How the data were processed

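Hippocampal RNA of male Sprague-Dawley rats was measured on 16 single-colour Agilent arrays, 4 for each of 4 groups: unstressed controls, and rats exposed to chronic mild stress (CMS, a run of small changing stressors) for 8 weeks and labelled depression-susceptible, anxiety-susceptible or insusceptible. How the stressed animals were sorted into groups, and whether the 4 arrays of a group hold RNA of 4 animals, is not given in the sources used here. Per the labels, ribosomal RNA was removed and the rest was amplified with random primers into Cy3-labelled cRNA.

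Per the file headers, the deposited spot values are intensity readings from Agilent Feature Extraction 11.0.1.1 with protocol GE1_1100_Jul11, which had subtracted background and removed spatial trends within each array; nothing had been done between arrays. The deposited value table holds log2 values whose columns share their quantiles, as found on the values themselves; the software behind it is not given in the sources used here, and it served only as an alternative. The headers name array design 026403 and an rn4 build cell without an annotation, so probes are given without positions. Gene symbols came from matching the RefSeq names of the probe targets to a gene name table of assembly GRCr8, used for names only: 14274 of the 15323 probes with a messenger RNA target matched, giving 13903 symbols.

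Control spots and spots marked as outliers on their array were left out, and the spots of a probe were averaged. The log2 processed signal of each array was then lowered by that array's 75th percentile. Of 24684 probes, the 17883 that were well above background on at least 4 of the 16 arrays were tested: 12466 for messenger RNAs, 1100 for RefSeq non-coding RNAs and 4317 with another target name. They cover 11344 symbols, and where a symbol had several probes the brightest was used. The number of arrays limits the precision. Between 62.2% and 74.6% of probes were well above background on an array, and 0 spots were saturated.

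A linear model with the 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests, Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05 on the adjusted p. There were 7 comparisons: each stressed group with control, the stressed groups with each other, and the mean of the stressed groups with control. An F test asked for any difference among groups. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the arrays and drew the plots.

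The arrays lie on 4 slides. Slides 1 and 2, scanned on day 1, each held 2 control and 2 depression-susceptible arrays; slide 3 held the anxiety-susceptible arrays and slide 4 the insusceptible arrays, both scanned on day 2. Arrays of 1 group on 1 slide differed by no more than repeated spots of a probe differ within an array (given with its values in the closing section). This check used probes with 3 spots, which carry RefSeq non-coding or other target names, so messenger RNA probes were not in it. Arrays of 1 group on 1 slide were therefore not counted as 4 independent samples. A second fit, chosen after seeing the data, averaged the arrays of a group on a slide and kept 6 samples: 2 control, 2 depression-susceptible, 1 anxiety-susceptible and 1 insusceptible. It has 2 residual degrees of freedom and assumes that the lone samples vary like the others. Standard errors (SE) are from this fit throughout, and log2 differences are the same in both apart from rounding. A gene is said to have risen or fallen only where limma's adjusted p was under the threshold in both fits, and a count is called held where this was so and the call with its sign also stood under quantile normalization. Fold differences against a group in which a probe was well above background on none of the arrays are written "at least". There the probe's signal was set no lower than the dimmest well-above-background signal of its array. These are lower bounds for the processed signal only. They need not hold under another background correction, and under normexp several of these differences were smaller or turned sign.

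Probes changed by known amounts in simulated data were used to test the steps for depression-susceptible against control over 17883 probes. With 16 arrays, 86% of the 100 probes changed 1.5-fold and 96% of the 100 changed 2-fold were called, beside 9 unchanged probes; with 6 samples these were 0% and 45%, beside 9 unchanged probes. The simulated arrays were drawn independently, without slides in common, and only 200 probes were changed. In the data, arrays of 1 slide resemble each other (correlation 0.463), so these shares and counts need not hold there. In a simulated list test 1 list other than the shifted one was called.

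The genes printed were chosen by a rule set before the data were examined. For each comparison with control it took the 10 largest rises and the 10 largest falls, and 5 and 5 for the other comparisons. They were taken among genes well above background on all 4 arrays of either group, under the threshold and without overlap of the arrays, with non-coding probes ranked apart. It added up to 4 members of each gene list with the smallest p, and in comparisons with control always Bdnf, Nr3c1, Nr3c2, Fkbp5, Crh, Fos and Gfap. Provisional symbols were counted, not named, and only part of these genes is printed. Some genes that the rule selects are not reported here.

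A set of 34 gene lists was fixed before the data were examined: glucocorticoid-induced genes, corticosteroid and CRH signalling, immediate early genes, neurotrophin and growth factor signalling, glutamate synapse, GABA synapse, interneuron markers, monoamine genes, neuropeptides, synaptic vesicle machinery, oligodendrocytes and their precursors, astrocytes, microglia, cytokines, interferon response, endothelial and mural cells, choroid plexus and ependyma, meninges, red blood cells, dentate gyrus neurons, CA1 to CA3 neurons, neurogenesis, thalamus and habenula, neocortex, striatum, heat shock and unfolded protein response, circadian clock, oxidative phosphorylation, ribosomal proteins, ubiquitin and proteasome, endocannabinoid, opioid and cholinergic signalling, histone and DNA modifying enzymes, and long non-coding RNAs. Lists with at least 5 tested members were tested with limma's camera and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; camera was repeated with an estimated correlation, and fry was run beside it. The adjusted p given with a list is camera's over 16 arrays unless another setting is named, and those arrays are not 16 independent samples, so the 6-sample values are given as well. The estimated correlation comes from the same 16 arrays and so from little more than the noise of spots and slides.

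The alternatives fixed before the data were examined were quantile normalization, the deposited value table, no filter, a filter on all 16 arrays, median centring, only the compared groups, array weights, an intensity trend with robust variance, the slide as a fixed or random block, the replicate number as a block, an unadjusted p under 0.05 with at least 1.5-fold, the first residual component, the mean of a gene's probes, fry, the estimated correlation, and leaving out each array. The 6-sample fit and its alternatives, cyclic loess, each slide alone, and normexp background correction of the median signal with an offset of 50 were chosen after seeing the data. The offset is added to every corrected signal, so log2 differences of dim probes shrink by design. It weighs more on the arrays of day 2, whose signal was lower. A call lost under normexp therefore does not show that a dim gene is unchanged. Scan day as a block was not run because it follows the groups, and normexp on the mean signal was not run because that column is not used here.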

Results

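The data are hippocampal transcript levels of male rats in 4 groups of 4 arrays: unstressed controls, and rats labelled depression-susceptible, anxiety-susceptible or insusceptible after 8 weeks of chronic mild stress. The probes cover messenger RNAs and long non-coding RNAs. Arrays of 1 group on 1 slide did not differ beyond the noise between spots, so errors rest on 6 samples: 2 control, 2 depression-susceptible, 1 anxiety-susceptible and 1 insusceptible. The last 2 groups have no spread of their own: their errors come from the differences between slides within the control and depression-susceptible groups and are assumed to hold for them. Across probes, the difference between slides 1 and 2 correlated at 0.951 between control and depression-susceptible arrays, and what the groups did not share was 0.787 times the spot noise. SE and adjusted p therefore measure the spread between slides and not the spread between animals. The 75th percentile of the processed signal was 2997 to 3382 on the control and depression-susceptible arrays, scanned on day 1, and 1077 to 1248 on the anxiety-susceptible and insusceptible arrays, scanned on day 2. Group, slide and day can be told apart only between depression-susceptible and control, whose arrays shared slides 1 and 2. On both slides the controls lay at positions 1 and 2 and the depression-susceptible arrays at positions 3 and 4. Position on the slide therefore follows the group. For every other comparison group and slide cannot be told apart. Neither can group and day, except that anxiety-susceptible and insusceptible arrays were all scanned on day 2.

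**Figure D1:**
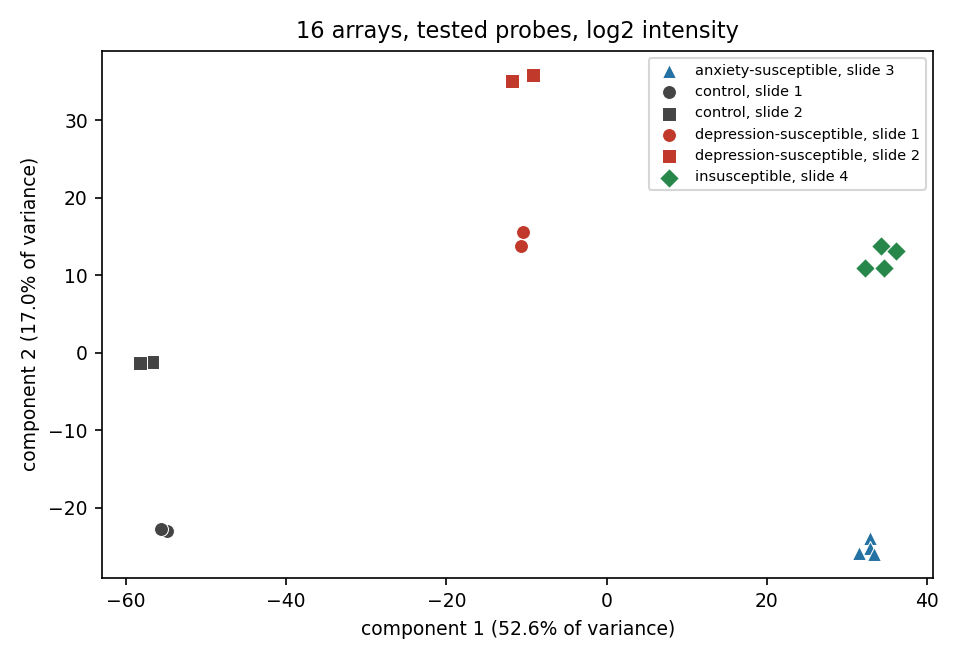
Each point is an array, placed by the first 2 principal components of the 17883 tested probes on the log2 scale, which hold 52.6% and 17.0% of the variance, and shaped by slide. The first component runs from the controls (-58.2 to -54.9) through depression-susceptible arrays (-11.8 to -9.18) to the anxiety-susceptible (31.5 to 33.3) and insusceptible arrays (32.3 to 36.1).

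The mean of the stressed groups was compared with control to ask what chronic mild stress changes whatever its behavioural outcome. Genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, were far lower after stress. Mfrp, a frizzled-related membrane protein of this epithelium, fell by 4.67 on the log2 scale (SE 0.06) and Sostdc1, a secreted antagonist of BMP and Wnt signalling, fell by 4.56 (SE 0.06). Bdnf, the neurotrophin that sustains hippocampal synapses, fell by 0.83 (SE 0.12, adjusted p = 0.0182), and Nr3c2, the mineralocorticoid receptor, fell by 0.60 (SE 0.08, adjusted p = 0.0151; -0.26 under quantile normalization). For Bdnf the groups differed. It stood at 0.68 and 0.90 in controls, 0.27 and 0.52 in depression-susceptible, -0.42 in anxiety-susceptible and -0.10 in insusceptible samples. Bdnf and Nr3c2 were both lowest in the groups scanned on day 2. Neither passed with 6 samples in depression-susceptible against control, where slides were shared. Sik1, a salt-inducible kinase, and Rasgrf1, a neuronal activator of Ras, were 3.06 (SE 0.11) and 2.93 (SE 0.12) higher. These genes were dim in the controls, and under normexp background correction the differences were 0.99 and 1.32 and no longer past the threshold. Nr3c1, the glucocorticoid receptor, differed by -0.09 (adjusted p = 0.359; 0.15 under quantile normalization), Gfap of astrocytes by -0.20 (adjusted p = 0.219; 0.07 under quantile normalization), Fkbp5 by 0.15 (adjusted p = 0.289), Crh by -0.31 (adjusted p = 0.125) and Fos by 0.43 (adjusted p = 0.0582), and none of these passed in the 6-sample fit.

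Members of gene lists are counted as past the threshold over all genes tested, and the count adjusted over the list alone was the same unless it is given. These counts and camera's adjusted p are over 16 arrays, and the values with 6 samples follow at the end of each account. All but 3 of the 9 red blood cell members are hemoglobin genes of close sequence. In every comparison the counts, median and adjusted p of that list may therefore count the same signal more than once. Choroid plexus genes were lower in the stressed mean (median -1.85, 21 of 24 members lower and 2 higher, adjusted p = 5.39e-10 in camera and 0.0026 with an estimated correlation). Red blood cell genes were higher (median 1.60, 7 of 9 higher and 1 lower, adjusted p = 0.00197, and 0.0449 with an estimated correlation), but the groups differed: the medians were 4.20 in depression-susceptible, 1.01 in insusceptible and -0.35 in anxiety-susceptible rats (5 of 9 lower and 1 higher, adjusted p = 0.458). Ubiquitin and proteasome genes, which degrade proteins, were lower (median -0.37, 37 of 48 lower and 1 higher, adjusted p = 3.59e-07, and adjusted p = 0.0676 with an estimated correlation). GABA synapse genes had a median of -0.32 (14 of 23 lower and 3 higher, adjusted p = 0.0356, and adjusted p = 0.414 with an estimated correlation). Synaptic vesicle genes had a median of -0.28 (20 of 32 lower and 5 higher, adjusted p = 0.0213, and adjusted p = 0.482 with an estimated correlation). Heat shock genes had a median of -0.30 (19 of 27 lower and 4 higher, and 6 higher adjusted over the list alone, adjusted p = 0.0391, and adjusted p = 0.594 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.34 (56 of 74 lower and 5 higher, adjusted p = 3.16e-06, and adjusted p = 0.493 with an estimated correlation). Ribosomal protein genes had a median of -0.33 that became 0.01 under quantile normalization (43 of 51 lower and 2 higher, and 44 lower adjusted over the list alone, adjusted p = 9.53e-06, and adjusted p = 0.652 with an estimated correlation). Under quantile normalization the calls of the GABA synapse, synaptic vesicle, heat shock, oxidative phosphorylation and ribosomal lists ended (adjusted p = 0.152, 0.314, 0.60, 0.754 and 0.955). With 6 samples 20, 7, 27, 10, 14, 10, 29 and 19 members of the 8 lists passed, in the order given, and camera's adjusted p were 1.53e-10, 0.00687, 9.27e-07, 0.0395, 0.0395, 0.0504, 1.89e-05 and 4.77e-05, so the heat shock call ended.

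In limma's test on 16 arrays 12589 probes passed, 6564 higher and 6025 lower; with 6 samples it was 3469 higher and 2803 lower, of which 2892 and 2555 were held under quantile normalization, and 1675 to 3047 in all with 1 control or depression-susceptible sample left out. Under normexp the split was 1435 higher and 3119 lower. The F test for any difference among the groups passed for 15465 probes on 16 arrays and for 3980 with 6 samples.

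Depression-susceptible rats were compared with control to find what accompanies this outcome of stress, and here both groups lay on the same slides. Hemoglobin genes, which carry oxygen in red blood cells, were among the largest rises: Hbb-b1 rose by 4.31 (SE 0.07; 2 against 2 samples; 19.8-fold; 4.32 on slide 1 and 4.29 on slide 2, adjusted p = 0.00222), Hba-a1 by 4.31 (SE 0.11) and Hbb by 4.30 (SE 0.09). Their sequences are close, so which copy a probe measured is uncertain, and under normexp Hba-a1 stood at 2.52. Choroid plexus genes fell: Mfrp (-5.57, SE 0.07, 47.6-fold lower), Sostdc1 (-5.2, SE 0.07, with -5.21 and -5.19 on the 2 slides) and the tight junction gene Cldn2 (-5.08, SE 0.07). The water channel gene Aqp1 (-4.33, SE 0.07), the potassium channel gene Kcnj13 (-4.17, SE 0.10) and the folate receptor gene Folr1 (-3.67, SE 0.09) fell with them. Genes that glucocorticoids induce fell as well, among them Nfkbia, an inhibitor of NF-kappaB (-1.08, SE 0.07, adjusted p = 0.0063), Ddit4, a brake on mTOR (-0.80, SE 0.08), Tsc22d3, known as GILZ (-0.58, SE 0.07), and the cell cycle inhibitor Cdkn1a (-0.58, SE 0.08). Dusp6, a dual-specificity phosphatase, fell by 1.15 (SE 0.13).

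Igf2, a growth factor made in choroid plexus and meninges, fell by 1.79 (SE 0.13), and Igfbp2, which binds it, fell by 1.89 (SE 0.07). Itgam, a microglial integrin, fell by 1.89 (SE 0.12). Gad2, which makes GABA, fell by 0.70 (SE 0.07), and the angiogenic factor gene Vegfa rose by 0.79 (SE 0.10). The interferon-stimulated gene Irf7 fell by 0.72 (SE 0.08). Some of the largest rises were of genes dim in the controls and were lost under normexp: Rasgrf1 (2.65, SE 0.13, 0.77 under normexp), Sik1 (2.42, SE 0.12, well above background on 1 of the 4 control arrays, 0.05 under normexp), RT1-M1-4 (at least 4.98-fold higher; -0.03 under normexp) and Grm2, a presynaptic glutamate receptor (at least 3.18-fold higher; -0.49 under normexp). Bdnf differed by -0.39 (SE 0.14, adjusted p = 0.166), Nr3c2 by -0.27 (adjusted p = 0.155; -0.02 under quantile normalization), Fkbp5 by -0.24 (adjusted p = 0.255), Fos by 0.39 (adjusted p = 0.155; -0.34 under normexp), Gfap by -0.37 (adjusted p = 0.152; 0.04 under quantile normalization), Nr3c1 by 0.08 (adjusted p = 0.585) and Crh by -0.09 (adjusted p = 0.688; -0.33 on slide 1 and 0.14 on slide 2), none of them past the threshold in the 6-sample fit. That fit leaves out the slide, and not passing in it does not show that a gene is unchanged. With the slide as a block of the 6 samples, chosen after seeing the data and leaving 1 residual degree of freedom and an error no larger than spot noise, Bdnf, Nr3c2, Fkbp5, Fos and Gfap passed (adjusted p = 0.0213, 0.0427, 0.0427, 0.0219 and 0.0321), and Nr3c1 and Crh did not (adjusted p = 0.297 and 0.625).

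**Figure D2:**
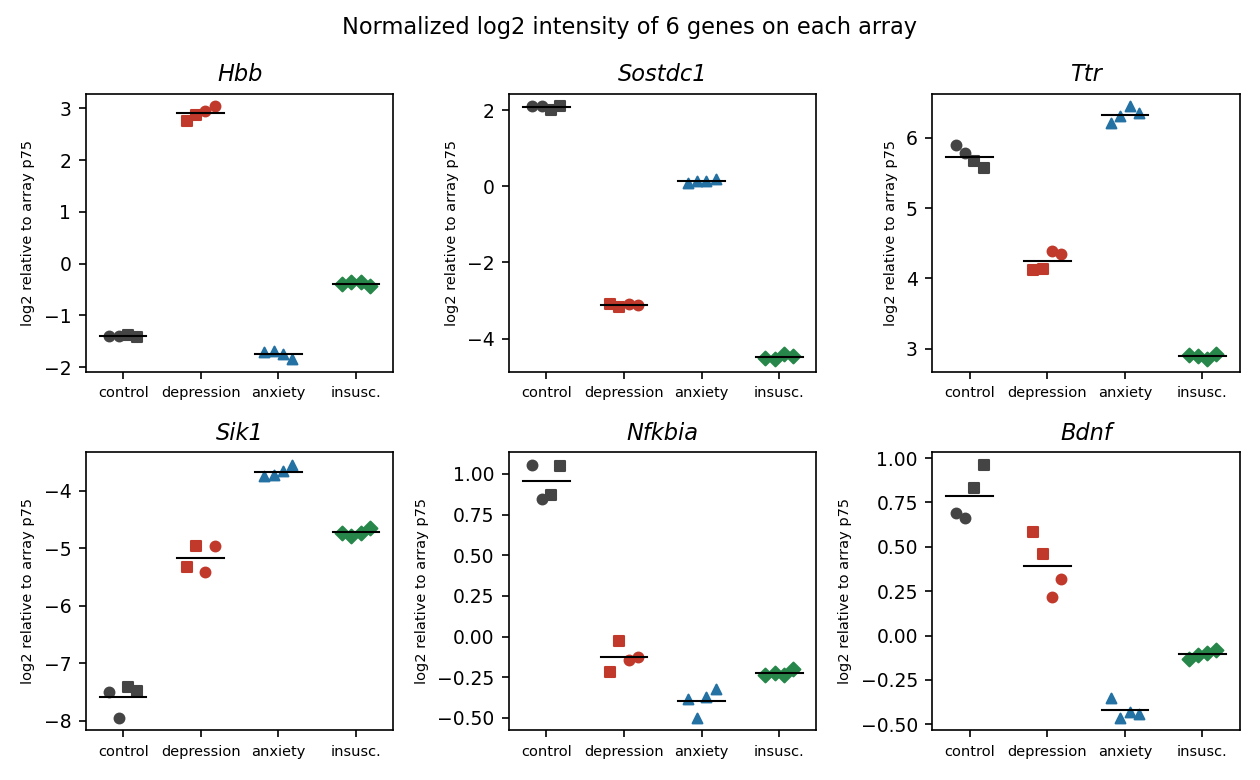
Points are the log2 signals of single arrays, relative to each array's 75th percentile, for Hbb, Sostdc1, Ttr, Sik1, Nfkbia and Bdnf in the 4 groups; points are shaped by slide and bars are means of 4 arrays. Hbb was 4.30 higher in depression-susceptible arrays than in controls and Sostdc1 was 6.55 lower in insusceptible arrays than in controls.

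In the list tests of depression-susceptible against control, red blood cell genes were higher (median 4.20, 4.16 and 4.21 on the 2 slides; 6 of 9 higher and 1 lower, adjusted p = 1.26e-07, and 0.00131 with an estimated correlation). This rests mainly on the hemoglobin members: Alas2, Ahsp and Epb42, which are not hemoglobins, differed by 2.35, -0.61 and 0.23. Choroid plexus genes were lower (median -2.28, -2.33 and -2.29 on the 2 slides; 21 of 24 lower and 1 higher, adjusted p = 3.78e-17, and 0.000192 with an estimated correlation). Glucocorticoid-induced genes were lower (median -0.31, -0.25 and -0.30 on the 2 slides; 16 of 25 lower and 1 higher, adjusted p = 0.00038, and 0.009 with an estimated correlation). Ubiquitin and proteasome genes were lower (median -0.33, and -0.11 under quantile normalization; 41 of 48 lower, 42 adjusted over the list alone, adjusted p = 1.03e-08, and 0.0301 with an estimated correlation); its member Psmb4 fell by 0.86 (SE 0.08, -0.53 under quantile normalization). GABA synapse genes had a median of -0.23 (13 of 23 lower, adjusted p = 0.00849, and adjusted p = 0.159 with an estimated correlation). Dentate gyrus neuron genes had 9 of 11 lower (adjusted p = 0.0406, and adjusted p = 0.159 with an estimated correlation). Heat shock genes had a median of -0.20 (15 of 27 lower and 2 higher, and 16 lower adjusted over the list alone, adjusted p = 0.0364, and adjusted p = 0.493 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.38, or -0.11 under quantile normalization (66 of 74 lower and 2 higher, and 68 lower adjusted over the list alone, adjusted p = 3.09e-11, and adjusted p = 0.231 with an estimated correlation). Ribosomal protein genes had a median of -0.40, or -0.07 under quantile normalization (44 of 51 lower and 1 higher, and 45 lower adjusted over the list alone, adjusted p = 4.22e-09, and adjusted p = 0.493 with an estimated correlation). Under quantile normalization the calls of the GABA synapse, dentate gyrus, heat shock and ribosomal lists ended (adjusted p = 0.0752, 0.107, 0.607 and 0.152). Endothelial and oligodendrocyte genes were then called higher (adjusted p = 0.0309 and 0.0161). With 6 samples 7, 20, 5, 5, 1, 0, 4, 5 and 4 members of the 9 lists called at first passed in limma, in the order given, with 1 at an unadjusted p under 0.05 beside the 0, and camera's adjusted p were 1.11e-06, 7.1e-17, 0.000868, 7.29e-08, 0.0129, 0.0301, 0.0433, 2.2e-09 and 7.29e-08.

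In limma's test 8918 probes passed on 16 arrays, 4078 higher and 4840 lower; with 6 samples it was 1289 higher and 508 lower, of which 1244 and 481 were held, and 291 to 682 in all with 1 of the 4 samples left out. With the slide as a block 10682 passed on 16 arrays and 6465 with 6 samples, and without a filter 991 passed with 6 samples. Under normexp 1686 passed. Of 1100 non-coding probes 177 were higher and 248 lower on 16 arrays, with 51 and 18 held.

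Anxiety-susceptible rats were compared with control to find what accompanies the other outcome of stress. Some genes of inhibitory transmission fell: Gad2 by 1.33 (SE 0.09; 1 against 2 samples, adjusted p = 0.00749), the GABA-A receptor genes Gabra4 by 1.21 (SE 0.12) and Gabrg1 by 1.27 (SE 0.11), and Npy, an anxiolytic peptide of interneurons, by 1.23 (SE 0.12). These are single genes: camera did not call GABA synapse genes (14 of 23 lower and 4 higher, adjusted p = 0.0612) or interneuron markers (9 of 22 lower and 7 higher, adjusted p = 0.822). Gad1, on both lists, went the other way, at 4.26 against 3.96 and 3.82 in controls. Nor are the falls particular to this group, since Gad2 and Npy fell in insusceptible rats too. Gabra4 stood at 0.47 and 0.63 in controls, -0.66 in anxiety-susceptible and -0.26 in insusceptible. For Gabrg1 these values were 0.14 and 0.005, -1.20 and -0.89. Bdnf fell by 1.21 (SE 0.17, adjusted p = 0.0216), and Nr3c2 by 0.72 (SE 0.11, adjusted p = 0.0241; -0.35 under quantile normalization). The stress-responsive transcription factor genes Atf3 (1.64, SE 0.09), Klf4 (0.67, SE 0.10) and Fos (1.13, SE 0.16, 0.58 and not past the threshold under normexp) rose, as single genes: immediate early genes as a list were not called (median -0.22 and mean 0.16, 8 of 21 higher and 11 lower, adjusted p = 0.982). Choroid plexus genes fell, Cldn2 by 2.52 (SE 0.08), Aqp1 by 2.49 (SE 0.09) and Sostdc1 by 1.94 (SE 0.09), and the glucocorticoid-induced genes Nfkbia and Tsc22d3 fell by 1.35 (SE 0.08) and 0.91 (SE 0.09). Among the largest falls was that of Fam111a, a protease gene linked to DNA replication (-3.83, SE 0.25).

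Deup1, which helps make the centrioles of ciliated cells, fell by 3.11 (SE 0.38), Wfs1, an endoplasmic reticulum gene of CA1 neurons, by 1.58 (SE 0.11), and Hbb-b1 by 0.50 (SE 0.09). Among the largest rises were those of genes dim in the controls whose calls ended under normexp: Pdia2, a protein disulfide isomerase (at least 8.26-fold; 0.97 under normexp), Sik1 (3.91, SE 0.15, 1.48 under normexp), the sodium channel gene Scn11a (at least 7.3-fold; 0.58 under normexp) and the collagen gene Col5a1 (3.08, SE 0.11, 1.35 under normexp). Nr3c1 differed by -0.21 (adjusted p = 0.181; 0.06 under quantile normalization), Fkbp5 by 0.20 (adjusted p = 0.333; 0.44 under quantile normalization), Crh by -0.31 (adjusted p = 0.236; -0.48 under quantile normalization) and Gfap by -0.01 (adjusted p = 0.958; 0.09 under quantile normalization), none past the threshold in the 6-sample fit.

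The lists called were choroid plexus genes (median -1.04, 20 of 24 lower and 3 higher, and 21 lower adjusted over the list alone, adjusted p = 2.27e-05, and 0.0414 with an estimated correlation) and, each lost with an estimated correlation, 3 lists of basic cell functions. Ubiquitin and proteasome genes had a median of -0.40 (36 of 48 lower and 1 higher, adjusted p = 8.04e-06, and adjusted p = 0.164 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.34, or -0.06 under quantile normalization, where the test pointed up (50 of 74 lower and 8 higher, adjusted p = 0.00224, and adjusted p = 0.723 with an estimated correlation). Ribosomal protein genes had a median of -0.28, or 0.08 under cyclic loess (35 of 51 lower and 4 higher, adjusted p = 0.00258, and adjusted p = 0.822 with an estimated correlation). Under quantile normalization the calls of these 3 lists ended (adjusted p = 0.102, 0.911 and 0.911). With 6 samples 18, 23, 18 and 10 members of the 4 lists passed, in the order given, and camera's adjusted p were 6.52e-06, 8.56e-06, 0.00693 and 0.00763. In limma's test 12756 probes passed on 16 arrays, 6552 higher and 6204 lower. With 6 samples it was 2750 higher and 2218 lower, or 2298 and 2834 under quantile normalization, with 2502 and 2147 held, and 1219 to 1365 in all with 1 control sample left out. Without a filter it was 1623 and 760. Under normexp 1542 were higher and 3140 lower. Of the non-coding probes 599 were higher and 235 lower on 16 arrays, with 182 and 68 held.

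Insusceptible rats were compared with control to ask what stress changes without either outcome. Among the largest falls were those of choroid plexus genes: Sostdc1 (-6.55, SE 0.09, 1 against 2 samples, adjusted p = 0.00246), Mfrp (-6.02, SE 0.09), Cldn2 (-5.69, SE 0.08), Aqp1 (-5.51, SE 0.09) and Kcnj13 (-4.72, SE 0.12). The transporter gene Slco1a5 was at least 49.1-fold lower. The activity-dependent transcription factor genes Nr4a1 (-0.62, SE 0.09), Junb (-0.63, SE 0.10) and Egr2 (-0.76, SE 0.08, -0.40 and not past the threshold under normexp) fell. Bdnf fell by 0.89 (SE 0.17, adjusted p = 0.0341), Nr3c2 by 0.80 (SE 0.11, adjusted p = 0.0199; -0.41 under quantile normalization), Npy by 1.36 (SE 0.12) and Gad2 by 1.13 (SE 0.09, -0.72 under normexp). Hemoglobin genes rose, Hbb-b1 by 1.0 (SE 0.09) and Hba-a2 by 1.53 (SE 0.09, 1.03 and not past the threshold under normexp).

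Igf2 fell by 2.34 (SE 0.16), the interferon-induced gene Ifi27 by 1.84 (SE 0.10), the antigen-presenting gene RT1-A2 by 1.30 (SE 0.15), Nfkbia by 1.18 (SE 0.08) and Wfs1 by 1.48 (SE 0.11), while Slc6a13, a GABA transporter gene of the meninges, rose by 2.23 (SE 0.15). Among the largest rises were again those of genes dim in the controls whose calls ended under normexp, Pdia2 (at least 5.59-fold; 1.40 under normexp), Rasgrf1 (3.15, SE 0.16, 1.85 under normexp) and Sik1 (2.86, SE 0.15, 1.43 under normexp). Fkbp5 differed by 0.50 (SE 0.14, adjusted p = 0.0672; 0.77 under quantile normalization), Nr3c1 by -0.14 (adjusted p = 0.333; 0.15 under quantile normalization), Crh by -0.52 (adjusted p = 0.0903), Fos by -0.23 (adjusted p = 0.322; 0.26 under normexp) and Gfap by -0.22 (adjusted p = 0.315; 0.10 under quantile normalization), none past the threshold in the 6-sample fit.

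Of the lists, choroid plexus genes were lower (median -2.40, 21 of 24 lower and 1 higher, and 2 higher adjusted over the list alone, adjusted p = 1.29e-10, and 0.00197 with an estimated correlation). The other 6 calls were lost with an estimated correlation. Immediate early genes, which neurons switch on when active, had a median of -0.42 (19 of 21 lower and 2 higher, adjusted p = 0.000779, and adjusted p = 0.125 with an estimated correlation). Red blood cell genes had a median of 1.01 (7 of 9 higher and 2 lower, adjusted p = 0.0253, and adjusted p = 0.125 with an estimated correlation). Synaptic vesicle genes had a median of -0.37 (20 of 32 lower and 4 higher, adjusted p = 0.00916, and adjusted p = 0.522 with an estimated correlation). Ubiquitin and proteasome genes had a median of -0.38 (35 of 48 lower and 3 higher, adjusted p = 8.42e-06, and adjusted p = 0.125 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.32, with the test pointing up under quantile normalization (50 of 74 lower and 8 higher, adjusted p = 0.000287, and adjusted p = 0.635 with an estimated correlation). Ribosomal protein genes had a median of -0.34, or 0.05 under quantile normalization (37 of 51 lower and 3 higher, adjusted p = 0.000351, and adjusted p = 0.803 with an estimated correlation). Under quantile normalization the calls of the red blood cell, synaptic vesicle, proteasome, oxidative phosphorylation and ribosomal lists ended (adjusted p = 0.215, 0.218, 0.161, 0.788 and 0.685). With 6 samples 19, 10, 6, 12, 22, 18 and 6 members of the 7 lists passed, in the order given, and camera's adjusted p were 5.98e-12, 0.00149, 0.0604, 0.0201, 1.82e-05, 0.000963 and 0.00117, so the red blood cell call ended. In limma's test 12972 probes passed on 16 arrays, 7142 higher and 5830 lower. With 6 samples it was 3213 higher and 2066 lower, or 2336 and 2532 under quantile normalization, with 2755 and 1964 held, and 1507 to 1950 in all with 1 control sample left out. Without a filter it was 6511 and 1679. Under normexp 1647 were higher and 3068 lower. Of the non-coding probes 514 were higher and 232 lower on 16 arrays, with 185 and 50 held.

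**Figure D3:**
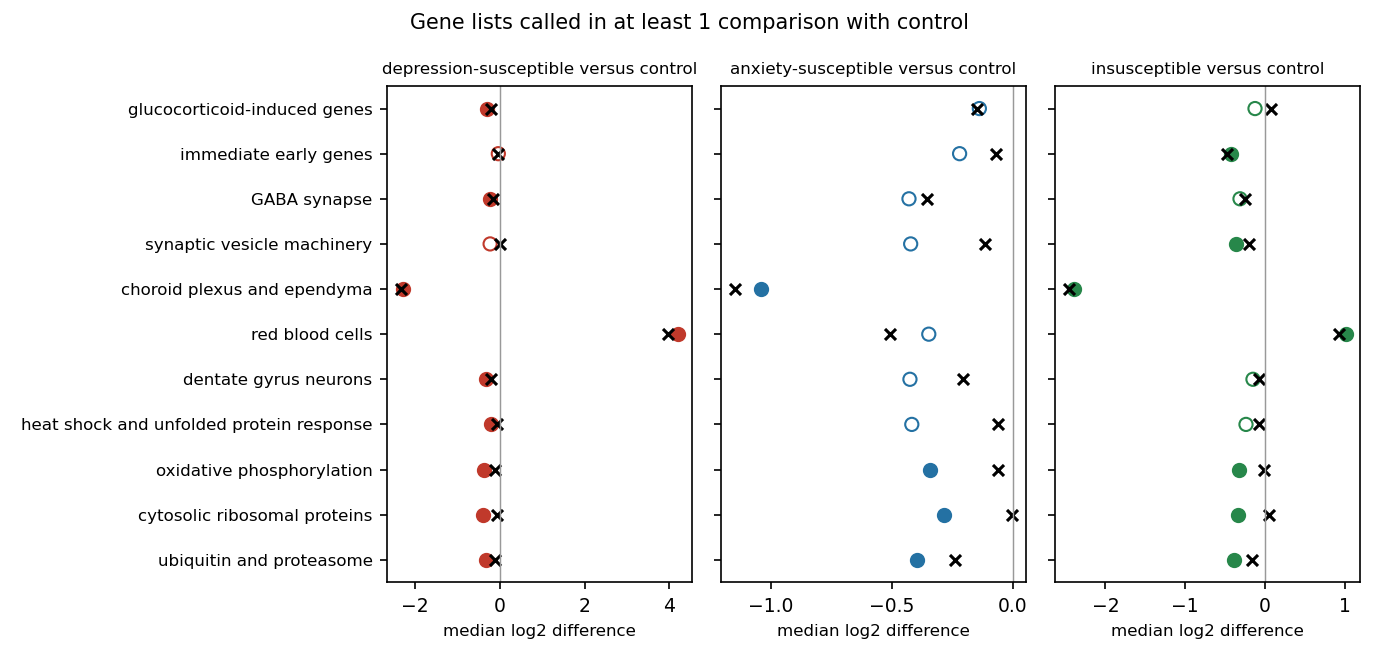
Points are the medians of the log2 differences over the members of each gene list, one panel per comparison, filled where camera called the list and open where not; crosses are the medians under quantile normalization, and the x axes differ between panels. Red blood cell genes lay at 4.20 and choroid plexus genes at -2.28 in depression-susceptible against control, while the ribosomal protein median of -0.34 in insusceptible against control was 0.05 under quantile normalization.

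Depression-susceptible and insusceptible rats had both been stressed, so their comparison asks what goes with the depression-like outcome itself. Hemoglobin genes rose, Hbb-b1 by 3.30 (SE 0.09; 2 against 1 samples, adjusted p = 0.0276) and Hbb by 3.29 (SE 0.12). Vegfb, a vascular growth factor gene dim in the insusceptible arrays, was at least 10.3-fold higher, with a difference of 0.88 that did not pass under normexp. Vegfb stood at -2.83 and -2.97 in controls, -3.05 in the depression-susceptible mean, -3.61 in anxiety-susceptible and -6.51 in insusceptible. The difference therefore lay in the low value of the lone insusceptible sample and not in a rise above control. Genes that passed on 16 arrays and not with 6 samples include Fkbp5, a glucocorticoid-induced brake on the glucocorticoid receptor (-0.73, SE 0.14, adjusted p = 0.0846), Cdkn1a (-0.65, adjusted p = 0.0761) and Klf4 (0.78, adjusted p = 0.0758). Red blood cell genes as a list were higher (median 2.67, 8 of 9 higher and 1 lower, adjusted p = 3.35e-06, and 0.00424 with an estimated correlation). Glucocorticoid-induced genes had a median of -0.38 (17 of 25 lower and 4 higher, adjusted p = 0.0339, and adjusted p = 0.0703 with an estimated correlation). Immediate early genes had a median of 0.39 (14 of 21 higher and 2 lower, adjusted p = 5.5e-05, and adjusted p = 0.0703 with an estimated correlation). Under quantile normalization cytokine and choroid plexus genes were called higher and oxidative phosphorylation genes lower (adjusted p = 0.0435, 0.0362 and 0.0362). With 6 samples 4, 0 and 0 members of the red blood cell, glucocorticoid-induced and immediate early lists passed in limma, with 12 and 12 at an unadjusted p under 0.05 for the last 2, and camera's adjusted p were 4.13e-07, 0.0863 and 0.000187, so the glucocorticoid-induced call ended. On 16 arrays 11092 probes passed in limma's test, 4763 higher and 6329 lower; median centring gave 5903 and 5192, and normexp 1990 and 1523. With 6 samples 9 were higher and 0 lower, against 2228 and 3286 at an unadjusted p under 0.05; quantile normalization gave 344 and 109, no filter 366 and 3799, and the filter on all 16 arrays 5 in all. With either depression-susceptible sample left out 0 passed in limma's test, against 3049 and 3538 at an unadjusted p under 0.05. Of the non-coding probes 152 were higher and 517 lower on 16 arrays.

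Anxiety-susceptible rats were compared with insusceptible rats in the same way. With 1 sample against 1, no error comes from the groups compared, so the adjusted p of single genes in the 6-sample fit rest wholly on the assumed spread. Choroid plexus genes were higher in the anxiety-susceptible sample: Sostdc1 by 4.61 (SE 0.10; 1 against 1 sample, adjusted p = 0.0286), Mfrp by 3.62 (SE 0.10), Cldn2 by 3.17 (SE 0.10, 1.58 and not past the threshold under normexp) and Aqp1 by 3.02 (SE 0.10, 1.63 and not past the threshold under normexp). Ttr, the thyroid hormone carrier that this epithelium secretes, was 3.43 higher (SE 0.19) without passing with 6 samples (adjusted p = 0.0567). Atf3 was 2.52 higher (SE 0.11, 1.5 and not past the threshold under normexp), while Ifit1, an interferon-induced blocker of translation, was lower (-2.94, SE 0.12, -1.69 and not past the threshold under normexp), as was Aox1, an aldehyde oxidase gene (-2.29, SE 0.10). Hbb-b1 differed by -1.5 (SE 0.10) without passing with 6 samples (adjusted p = 0.0658).

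As lists, choroid plexus genes were higher (median 1.09, 21 of 24 higher and 1 lower, adjusted p = 1.19e-23, and 3.6e-05 with an estimated correlation) and red blood cell genes lower (median -1.36, 6 of 9 lower, adjusted p = 1.53e-05, and 0.00495 with an estimated correlation). Immediate early genes were higher (median 0.36, 12 of 21 higher and 4 lower, adjusted p = 8.64e-06, and 0.0256 with an estimated correlation). Glucocorticoid-induced genes were lower (median -0.23, 13 of 25 lower and 2 higher, adjusted p = 0.00912, and 0.0258 with an estimated correlation). Endothelial and mural cell genes were lower (median -0.16, 13 of 21 lower, 14 adjusted over the list alone, adjusted p = 0.00628, and 0.0256 with an estimated correlation). Meningeal genes had a median of -0.27 (10 of 17 lower and 4 higher, adjusted p = 0.0429, and adjusted p = 0.151 with an estimated correlation), and their call ended under quantile normalization (adjusted p = 0.0694). These calls and member counts take the 4 arrays of a group as 4 samples, although each group is 1 sample. With 6 samples 5, 0, 1, 0, 0 and 0 members passed in limma, in the order given, against 21, 5, 11, 5, 2 and 11 at an unadjusted p under 0.05. Camera's adjusted p were then 2.44e-26, 1.14e-05, 9.05e-06, 0.0248, 0.0248 and 0.0296, and they rest on the same assumed spread as the single genes. On 16 arrays 6478 probes passed in limma's test, 2670 higher and 3808 lower; cyclic loess gave 3586 and 2938, and normexp 510 in all. With 6 samples 15 were higher and 2 lower, or 39 and 15 under quantile normalization. Without a filter 0 passed in limma with 6 samples, against 2659 at an unadjusted p under 0.05, so every single-gene call of this comparison then ended. Of the non-coding probes 278 were higher and 181 lower on 16 arrays.

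Depression-susceptible and anxiety-susceptible rats were compared to separate the outcomes of stress from each other. Hemoglobin genes rose, Hbb-b1 by 4.81 (SE 0.09; 2 against 1 samples; 28-fold, adjusted p = 0.0101) and Hbb-bs by 4.77 (SE 0.09), and so did Fam111a, by 4.56 (SE 0.25). Fam111a stood at -0.82 and -0.49 in controls, -0.14 and 0.29 in depression-susceptible samples, -4.49 in anxiety-susceptible and -0.77 in insusceptible. Its difference therefore lay mainly in the low value of the lone anxiety-susceptible sample. Choroid plexus genes fell, Sostdc1 by 3.26 (SE 0.09) and Mfrp by 3.17 (SE 0.09), and Cnmd, which codes for the cartilage protein chondromodulin, fell by 3.11 (SE 0.13). The urea transporter gene Slc14a2 was at least 4.41-fold lower, with a difference of -1.68 that did not pass under normexp. It stood at -8.87 and -8.67 in controls, -9.74 and -9.91 in depression-susceptible samples, -6.20 in anxiety-susceptible and -8.35 in insusceptible. Here too the lone anxiety-susceptible sample stood apart. As lists, red blood cell genes were higher (median 4.07, 8 of 9 higher and 1 lower, adjusted p = 1.3e-06, and 0.00197 with an estimated correlation) and choroid plexus genes lower (median -1.27, 22 of 24 lower, adjusted p = 4.21e-13, and 0.000731 with an estimated correlation). Under cyclic loess oxidative phosphorylation and ribosomal genes were called lower (adjusted p = 0.0174 and 0.0106). With 6 samples 5 and 6 members of the red blood cell and choroid plexus lists passed, and camera's adjusted p were 1.57e-07 and 6.31e-14. On 16 arrays 11024 probes passed in limma's test, 5212 higher and 5812 lower, and 3161 passed under normexp. With 6 samples 23 were higher and 32 lower, or 941 and 510 under quantile normalization and 6 and 2 without a filter. With either depression-susceptible sample left out 0 passed in limma's test, against 3444 and 3507 at an unadjusted p under 0.05. Of the non-coding probes 152 were higher and 638 lower on 16 arrays.

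The comparisons with control were set side by side to ask which changes the stressed groups share. With 6 samples 1007 probes were higher and 333 lower in all 3 stressed groups, of which 939 and 314 were held, against 35.6 and 7.28 for independent calls. On 16 arrays the counts were 2886 and 3336, against 597 and 547 for independent calls. The values for independent calls take no account of the shared controls. Simulated unchanged groups that shared the controls gave 0, but hardly any probe is called in such groups, so this 0 decides nothing. Across probes, which are not independent replicates, the log2 differences from control correlated at r = 0.854 between anxiety-susceptible and insusceptible, 0.758 between depression-susceptible and insusceptible and 0.679 between depression-susceptible and anxiety-susceptible. Without a filter they were 0.834, 0.494 and 0.554, so the order of the last 2 turned. Simulated unchanged groups against the same controls gave 0.503, 0.50 and 0.501, for the filtered probes, with covariances of 0.00965, 0.00952 and 0.00960 beside the observed 0.409, 0.263 and 0.231. The simulated groups hold no difference of slide or day, while the anxiety-susceptible and insusceptible arrays share a scan day that no control array has, so day and stress cannot be told apart in what these groups share. With separate control arrays for each comparison, split as control arrays 1 and 2 against 3 and 4, the correlations were 0.746, 0.614 and 0.542.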

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

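All tests of explanations in this part, and the 6-sample fit, were chosen after the results they concern had been seen.

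Some gene lists differed between the stressed groups in a direct test. Between anxiety-susceptible and insusceptible these were choroid plexus genes (median log2 difference 1.09), red blood cell genes (-1.36), immediate early genes (0.36), glucocorticoid-induced genes (-0.23) and endothelial and mural cell genes (-0.16). Between depression-susceptible and anxiety-susceptible they were red blood cell genes (4.07) and choroid plexus genes (-1.27), and between depression-susceptible and insusceptible red blood cell genes (2.67). These calls are over 16 arrays. With 6 samples camera called them as well, with 0.0248 as the largest adjusted p, but the anxiety-susceptible and insusceptible groups are then 1 sample each, so the differences have no replicate within these groups. In each of these comparisons slide and group cannot be told apart.

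Single arrays lay apart from the other 3 of their group in 12 of 191 groups of 4 arrays tested, or 6.28%. Chance would give 5% for 4 independent arrays. Control and depression-susceptible arrays lie in pairs on 2 slides, so the 5% is no measure of chance for them. The gap to the nearest array, as a share of the group's range, was 0.872 for Sostdc1 on depression-susceptible array 2 and 0.975 for Sostdc1 on control array 3. For Cdkn1a, Gabra4 and Gabrg1 on control array 1 it was 0.943, 0.899 and 0.843, and for Sik1, Irf7 and Grm2 on control array 2 it was 0.832, 0.875 and 0.908. It was 0.854 for Gad2 on control array 3, 0.833 for Npy on anxiety-susceptible array 1, 0.904 for Deup1 on anxiety-susceptible array 4 and 0.856 for Slc6a13 on insusceptible array 2. In 75% of these the whole range of the 4 arrays was under 0.3 log2.

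The first pattern weighed is that groups differ at many probes while arrays of 1 group on 1 slide differ by no more than their spots. Over 1391 probes with 3 spots each, the variance between such arrays was 0.516 to 1.01 times that expected from the spots in 16 pairs, and 6.35 to 9.16 times in the 8 pairs on different slides. Of the 8357 probes with 3 spots, 1725 had RefSeq non-coding and 6632 other target names. Messenger RNA probes were therefore not in this check. The slides do not explain the difference between depression-susceptible and control, since across probes, which are not independent replicates, it correlated at 0.876 between slide 1 and slide 2. Position on the slide followed the group on both slides, so position and group cannot be told apart by this. Between anxiety-susceptible and insusceptible the spread of differences was 1.23 times that between slides 1 and 2 with the group held fixed, so slide and stress outcome cannot be told apart there. Open as well is that all arrays of a group may hold 1 RNA, since after removing what the slides share the variance between slides was 0.787 times the spot noise; biological differences between the stress outcomes stay untested beside it.

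The second pattern is the rise of red blood cell genes in depression-susceptible rats. A difference between slides is excluded by the within-slide medians, of which the lower was 4.16, and scaling by the median of 3.97 under quantile normalization. More blood left in the tissue may be the source, and what keeps it open is that the test is undecided: the members that are not hemoglobins, chosen after their values were seen, went opposite ways. Against control Alas2 differed by 2.35, Ahsp by -0.61 and Epb42 by 0.23, well above background on 15, 15 and 5 arrays. Against the other stressed groups all 3 were higher, as the hemoglobins were. The differences were 1.99, 0.42 and 0.97 from insusceptible and 2.40, 0.45 and 0.84 from anxiety-susceptible rats. Their median against control was 0.23, and 0 of these 3 were well above background on all 16 arrays. An effect of the depression-susceptible state on hemoglobin expression in brain cells is an open alternative that these data do not separate from blood.

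The third pattern is the fall of choroid plexus genes in stressed rats. Slides are excluded for depression-susceptible rats by the within-slide medians, of which the higher was -2.29. Ventricle wall carried along with the control tissue would bring ependyma. The ependymal members Drc12 and Tmem212, chosen after their values were seen, had a median of 0.12 in depression-susceptible against control. The other 22 members had -2.37. Against control Drc12 and Tmem212 differed by 0.83 and 0.61 in anxiety-susceptible rats and by 0.14 and 0.06 in insusceptible rats. The list was lower in both. Yet Deup1 of ciliated cells stood at 0.92 and 0.36 in depression-susceptible samples on slides 1 and 2, below 2.52 and 1.89 in controls. Deup1 is not on the list and was chosen here after its values were seen, so it decides nothing alone. Between anxiety-susceptible and insusceptible, Drc12 and Tmem212 were 0.69 and 0.55 higher, as the list was. In the comparisons with control these 2 members did not fall with the list, and in this one they moved with it. They therefore do not decide whether ventricle wall was carried along. A different amount of choroid plexus tissue in the dissected hippocampus could lower all these genes; Ttr, the most abundant product of that tissue and in this comparison chosen after its values were seen, was 0.60 higher in anxiety-susceptible rats than in control while the list was lower, yet in depression-susceptible rats it differed by -1.48 and in insusceptible rats by -2.84, down with the list. This keeps the amount of tissue open, and a change of choroid plexus transcription under stress is untested beside it.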

How the results depend on the processing

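The 6-sample fit with all its alternatives, cyclic loess, normexp on the median signal and each slide alone were chosen after seeing the data; the other alternatives were fixed before. The cause of a change was not tested unless it is named.

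Comparisons are given in the order depression-susceptible, anxiety-susceptible and insusceptible against control, depression-susceptible against insusceptible, anxiety-susceptible against insusceptible, depression-susceptible against anxiety-susceptible, and the stressed mean against control. Averaging the arrays into 6 samples left 1797, 4968, 5279, 9, 17, 55 and 6272 probes, because fewer samples are counted. An unadjusted p under 0.05 with at least 1.5-fold left 1942, 5194, 5557, 2867, 1356, 2912 and 3745, because small differences are dropped. Normexp left 1686, 4682, 4715, 3513, 510, 3161 and 4554. Its offset of 50 shrinks the differences of dim probes by design, and how much of the loss this explains was not tested. Array weights gave 10251 between anxiety-susceptible and insusceptible, the slide as a random block gave 7270 for depression-susceptible and 1920 for anxiety-susceptible against insusceptible, and slide 2 alone gave 5734 for depression-susceptible against control; the causes of the first pair were not tested, and the last holds fewer arrays. Under quantile normalization, the deposited value table, no filter, the filter on all 16 arrays, median centring, only the compared groups, the variance trend, the first residual component and cyclic loess, every 16-array count stayed within 1.5 times.

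In the 6-sample fit, quantile normalization gave 453, 54 and 1451 for the comparisons between stressed groups, cyclic loess 384, 41 and 808, and the authors' value table counts of 398, 48 and 1482, in the order above. Without a filter the counts were 991, 2383 and 8190 against control and 4165, 0 and 8 between stressed groups; beside the 0 in limma, 2659 passed at an unadjusted p under 0.05. The filter on all 16 arrays gave 5 for depression-susceptible against insusceptible and 289 against anxiety-susceptible, and the trend with robust variance gave 20, 55 and 1215 between stressed groups. The slide as a block gave 6465 for depression-susceptible against control, and Bdnf, Nr3c2, Fkbp5, Fos and Gfap then passed, as they did on 16 arrays. The causes of these were not tested. Leaving out 1 sample (leave-one-out) gave 291 to 682, 1219 to 1365 and 1507 to 1950 against control and 1675 to 3047 for the stressed mean. Without either depression-susceptible sample, 0 to 0 passed in limma against both other stressed groups, with 3049 to 3538 at an unadjusted p under 0.05 against insusceptible and 3444 to 3507 against anxiety-susceptible. Fewer samples explain these.

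Leaving out 1 array at a time, with all other arrays kept, gave 8421 to 8758, 12226 to 12534, 12406 to 12822, 10314 to 10890, 5281 to 5582, 10239 to 10714 and 12046 to 12660 probes, and 15033 to 15460 in the F test. The F test over 6 samples gave 3980.

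With the replicate number as a block, which pairs arrays that share only a number, the counts were 8375, 12390, 12629, 10557, 5598, 10502 and 12198, the F test gave 15007, and the counts of lists did not change; Nr3c1 in the stressed mean was the only named gene to lose its call.

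Gene lists called by camera numbered 9, 4, 7, 3, 6, 2 and 8. An estimated correlation left 4, 1, 1 and 1 of the first 4 and 2 in the stressed mean. Quantile normalization gave 1 for anxiety-susceptible and 2 for insusceptible against control, 6 for depression-susceptible against insusceptible and 3 in the stressed mean; cyclic loess gave 2, 2, 5 and 3 for these and 4 for depression-susceptible against anxiety-susceptible. Here the scaling removed a trend with brightness: between dim and bright probes the medians ran from 0.53 to -0.28 in insusceptible against control. Fry, which asks whether a list's genes move, on balance, one way and compares them with no other genes, called 28, 27, 28, 22, 19, 25 and 27. Leaving out 1 array gave 7 to 9, 4 to 7, 7 to 8, 3 to 4, 6 to 6, 2 to 2 and 7 to 8, with the 7 for anxiety-susceptible against control coming without control replicate 3; the cause was not tested.

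Probes changed alike in all 3 stressed groups numbered 6222 on 16 arrays and 1340 with 6 samples, because fewer samples are counted. The correlations of depression-susceptible with anxiety-susceptible and with insusceptible were 0.554 and 0.494 without a filter; the cause was not tested. With the controls split 1 and 2 against the others they were 0.542 and 0.614, and 0.746 between anxiety-susceptible and insusceptible, because that split follows the slides.

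Of 3073 alternative values of 132 gene results, 2952 kept direction and side of the threshold, 88 were no longer past it (25 with 6 samples and 39 under normexp), 5 came to pass it and 28 turned sign. Under quantile normalization Gfap turned to 0.042, 0.085, 0.097 and 0.075 in the comparisons with control, the stressed mean last, and Nr3c1 to 0.058 for anxiety-susceptible, 0.15 for insusceptible and 0.15 for the stressed mean. The deposited value table gave Gfap 0.043, 0.086, 0.097 and 0.075 and Nr3c1 0.057, 0.15 and 0.15. Cyclic loess gave Gfap 0.42 for anxiety-susceptible, 0.28 for insusceptible and 0.23 for the stressed mean, and Nr3c1 0.082 and 0.10 for the last pair. Gfap in anxiety-susceptible against control also turned to 0.025 with array weights and 0.024 under normexp. Leaving out 1 array gave it -0.037 to 0.036, with 0.036 without control replicate 1 and 0.0068 without anxiety-susceptible replicate 2. Normexp turned RT1-M1-4 to -0.031, Grm2 to -0.49 and Fos to -0.34 in depression-susceptible and Fos to 0.26 in insusceptible against control. Crh in depression-susceptible against control turned to 0.14 on slide 2 alone. The causes were not tested.

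Signal over background limits the rises of dim genes. A probe near background in the controls has no firm lower level, so its fold is a bound and depends on the background correction, and arrays of day 2 had a lower signal, with a ratio of 2.48 between the days' medians. Scan day as a block was not run because it follows the groups, and normexp on the mean signal was not run because that column is not used here.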

Other observations

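The tests by splits of the arrays, the 6-sample fit and normexp were chosen after seeing the data.

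Further genes were named singly, without a test of them as a set, and camera called neither the cytokine nor the interferon list in any comparison with the 75th percentile scaling. Isg15, a ubiquitin-like interferon product, fell by 0.82 (SE 0.08) in depression-susceptible against control, with -1.14 and no call under normexp. Cxcl10, a chemokine that draws T cells, was 0.91 higher (SE 0.08), with 0.19 and no call under normexp, and it was 1.87 higher than in insusceptible rats without passing with 6 samples (adjusted p = 0.066). Irf7, a master regulator of interferon, differed by -1.02 from insusceptible rats without passing with 6 samples (adjusted p = 0.0758). Ifit1 fell by 1.73 (SE 0.10) in anxiety-susceptible against control, with -0.75 and no call under normexp.

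In depression-susceptible against control Slco1a5, an organic anion transporter gene, fell by 4.87 (SE 0.11), Slc4a5, a bicarbonate transporter gene, by 4.31 (SE 0.16), and Pon1, which breaks down oxidised lipids, by 4.13 (SE 0.08). Cltrn, which traffics amino acid transporters, was at least 52.9-fold lower in insusceptible rats than in control. Between anxiety-susceptible and insusceptible rats Slco1a5 was at least 12.0-fold and Pon1 at least 5.1-fold higher, with 1.16 and 0.36 and no call under normexp. Th, which makes dopamine, was 0.92 higher (SE 0.08) in depression-susceptible against control, with 0.31 and no call under normexp.

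In depression-susceptible against control, the comparison with both groups on the same slides, the lists that camera called in no comparison with the 75th percentile scaling had these adjusted p. They were 0.456 for corticosteroid and CRH signalling (5 of 15 lower and 1 higher), 0.791 for neurotrophin signalling, 0.386 for the glutamate synapse, 0.279 for interneuron markers, 0.765 for monoamine genes and 0.281 for neuropeptides (12 of 27 lower and 5 higher). Glial and immune lists had 0.78 for oligodendrocytes (0.016 and higher under quantile normalization), 0.527 for their precursors, 0.331 for astrocytes, 0.396 for microglia, 0.276 for cytokines and 0.432 for the interferon response. Neuronal lists had 0.671 for CA1 to CA3, 0.815 for neurogenesis, 0.586 for thalamus and habenula, 0.56 for neocortex and 0.456 for striatum. The rest had 0.449 for the circadian clock, 0.864 for endocannabinoid, opioid and cholinergic signalling and 0.426 for histone and DNA modifying enzymes. The smallest adjusted p of these lists in any comparison on 16 arrays was 0.0718, for microglia in anxiety-susceptible against control, where 15 of 27 were lower and 1 higher. Of the 42 long non-coding RNAs on their list 2 were tested, too few for a test as a set.

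Other splits of the arrays do not decide whether chance can be excluded. Over the probes with 3 spots, arrays of a group on a slide differ by no more than spot noise, so a split that puts such arrays on both sides has to give few calls. For the counts of probes, 1 of 35 splits, the real one, gave as many in each comparison of 2 groups. The real counts and the highest of the other splits were 12756 and 3 for anxiety-susceptible against control, 12972 and 1 for insusceptible against control, 11092 and 3 for depression-susceptible against insusceptible, 6478 and 1 for anxiety-susceptible against insusceptible, and 11024 and 3 for depression-susceptible against anxiety-susceptible. For depression-susceptible against control they were 8918 and 2903, the latter from the split that follows the slides, and with the slide as a block the real count was 10682. Of 100 splits drawn, the stressed mean had 12589 and 6754 and the F test 15465 and 9593. In both, 1 of the 100, the real one, gave as many.

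The splits decide no more for the counts of lists called. With the real count first and the highest other split second, as many lists were called in 5 of 35 splits for depression-susceptible against control (9, 10), 9 of 35 for anxiety-susceptible against control (4, 6) and 5 of 35 for insusceptible against control (7, 8). It was 13 of 35 for depression-susceptible against insusceptible (3, 4), 3 of 35 for anxiety-susceptible against insusceptible (6, 7), 18 of 35 for depression-susceptible against anxiety-susceptible (2, 5) and 13 of 100 for the stressed mean (8, 10).

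Choroid plexus and meningeal lists share Igf2 and Igfbp2, so they are not independent. Across the 1391 probes with 3 spots, which are not independent replicates and leave out messenger RNAs, the difference between slides 1 and 2 in controls correlated with that in depression-susceptible arrays at 0.951.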
